A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

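The arrays were 2-colour spotted yeast arrays on which, per the labels, 6240 open reading frames were printed in duplicate. The deposited raw values are spot intensities, and per the file headers they were measured with ImaGene 6.0.1 with 1 file per channel, so 90 files made up 45 arrays. The deposited table holds log2 ratios per group. The strain was W303-1A with GPD1 disrupted by TRP1 and GPD2 by URA3, carrying rat AQP9, grown in synthetic medium with 2% glucose. Cells met 1 M glycerol or erythritol for 5, 10 or 20 min, xylitol for 5, 10, 20 or 30 min, or sorbitol for 5, 10, 20, 30, 60 or 90 min. Each time point had 3 arrays except sorbitol at 20 and 90 min and xylitol at 20 min, which had 2. The reference on every array was the same strain before exposure. How many cultures stood behind the reference is not given in the sources used here, nor whether the arrays of a group came from separate cultures. Scanner settings and the version of limma named in the submitters' notes are not given either.

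Signal mean and background median were corrected with normexp at an offset of 50, and the log2 ratios were normalized by global loess within each array with limma 3.58.1 in R 4.3.3. Control spots (442 of 13056 on an array) and spots with the poor or negative flag had weight 0 in the loess, poor and negative spots were then dropped, and spots with the empty flag were kept. Duplicate spots were averaged. This gave 6293 probes, of which 5716 were matched to the yeast annotation by locus tag and 577 kept the name in the files, with 3.84% of values missing. Tables and figures were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

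Per the labels, treated RNA was in Cy3. The values pointed the other way. Among the 300 genes that differed most between groups, the median slope of the channel 2 intensity on the ratio was 0.886 and that of channel 1 was -0.114, and channel 2 varied more between groups for 85.7% of them. Without the sorbitol arrays these values were 0.739, -0.261 and 66.7%, and for glycerol alone 0.717, -0.283 and 60.7%. The deposited table is also channel 2 over channel 1. Channel 2 was therefore taken as the treated sample, which is the likely direction and opposes the dye entry; every sign turns if the entry is literal. No array was a dye swap.

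One linear model with 16 groups was fitted to all 45 arrays with limma and moderated (prior degrees of freedom 9.53). A gene was called against the reference at an adjusted p (Benjamini and Hochberg) under 0.05 and an absolute log2 of at least 1. Differences between polyols at the same time, and moderated F tests over the times of 1 polyol, were called at an adjusted p under 0.05. The p-values measure only the spread between these samples. The ratio against 0 leaves out the reference's own spread, and the number of arrays limits precision. Where a channel was not above background, a fold is given as a bound from the per-channel values after loess and Aquantile scaling, and such bounds are open to dye bias without dye swaps. Correlations between arrays are across genes, and genes are not independent replicates.

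The 24 gene lists were osmostress, glycerol metabolism, sorbitol and xylitol metabolism, Msn2/4 targets, trehalose and glycogen, heat shock, oxidative stress, ribosomal proteins, ribosome biogenesis, cell wall integrity, mating, G1/S, histones, G2/M, M/G1, ergosterol, glycolysis, hexose transport, respiration, phosphate, Gcn4 targets, iron, proteasome and the strain markers. Lists were tested with cameraPR on the moderated t at the preset correlation of 0.01 and, as an alternative, with the correlation estimated from the arrays. Counts of list members are given over all genes and adjusted over the list alone.

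Genes were named by a rule. Named were STL1, GRE2, GPP1, GPP2, HOR7, RTC3, CTT1 and HSP12 and the strain genes GPD1, GPD2, TRP1, URA3 and LEU2, the 6 largest rises and 4 largest falls of each polyol at its time with most calls among genes with the same sign on every array of the group, and up to 4 called members of each list. Named too were up to 5 genes per direction for sorbitol minus glycerol and 3 for the other differences, and the 5 genes with the largest range over time. The groups, lists, thresholds, naming rule and first set of alternatives were chosen before the data were examined.

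The alternatives were no background correction, print-tip loess, the dimmest 25% of genes left out, another call rule (no limit on the log2 against the reference, and at least 2-fold elsewhere), a block for replicate number, a block for scan batch, each array left out in turn (in a group of 2 this leaves 1 array, and the spread comes from the other groups), the estimated correlation and the deposited table. The block for scan batch rests on 1 array at 5 and 10 min of glycerol and at 20 min of sorbitol. The other arrays of these groups shared no batch with another group. Leaving out weak arrays and keeping poor-flagged spots were chosen after the data were seen. Using only the first or only the second scan could not be run, because the file pairs are channels and not repeated scans. Of the deposited table's columns 13 of 16 were used. The rule for use (a correlation of at least 0.7 and a slope of at least 0.5 with the raw ratio of signal means of the same arrays) was set after the values were seen, and left out sorbitol at 10 min (correlation 0.57, slope 0.23), 20 min (correlation -0.01) and 90 min (correlation 0.54, slope 0.33). Against the normalized values sorbitol at 90 min would have passed (correlation 0.90, slope 0.53), and erythritol at 5 min (correlation 0.68) and glycerol at 10 min (slope 0.45) would not. Column medians of the table lay between -0.02 and 0.00, its scale and direction were clear, and its centring stays unknown.

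On simulated spot intensities with the spread of these arrays and a known difference in 200 of the brighter genes, 93% of genes at log2 1.5 and 99% at log2 3 were called at 20 min of erythritol, and 90% and 100% at 20 min of xylitol with 2 arrays. For erythritol minus glycerol at 20 min the shares were 83% and 98%, and for the F test over erythritol times 85% and 98%. Among 5966 simulated genes without a difference, 4 were called at 20 min of erythritol. A simulated list shift of -0.40 was called (adjusted p = 4.57e-06 by cameraPR). The simulation gave each gene the same spread on all arrays, with a constant background level and independent genes. It held no weak arrays and no scan batches. The shares and the list result therefore do not describe weak arrays, groups with a wide spread or correlated genes.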

Results

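Yeast cells that carry rat AQP9 and cannot make glycerol answered 1 M erythritol, xylitol and sorbitol with a large rise of osmostress genes and a fall of ribosomal genes. Glycerol, the smallest of these 4 sugar alcohols, was followed only to 20 min. At that time its osmostress genes lay lower than in erythritol (median 1.03 against 2.28), while at 10 min they lay higher than in sorbitol (0.80 against 0.11). The 45 arrays covered 16 combinations of polyol and time, each set against the same strain before exposure. All log2 values take channel 2 as the treated sample. This likely direction opposes the dye entry in the labels, and all signs turn if that entry is literal. Signal over background ranged from 1.19 to 7.81 in channel 1 and from 1.05 to 7.50 in channel 2, and between 3.59% and 24.9% of spots per array had the poor flag. Signal was under 1.3 times background on 5 arrays, all of them among the 16 sorbitol arrays, at 10 min (2 arrays), 20, 30 and 60 min (1 array each). Correlations between replicate arrays across genes ran from -0.21 to 0.14 at 10 min of sorbitol and from 0.82 to 0.87 at 20 min of erythritol.

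The marker TRP1 stood above the reference in most groups. The probe of GPD1, which encodes the main glycerol 3-phosphate dehydrogenase, was above background on 11 of 45 arrays in channel 1 and 6 in channel 2, with group means from -0.72 to 0.80. The probe of GPD2, its paralogue, was above background on 35 and 22 arrays and was called in 1 group, 10 min of glycerol (log2 -1.17, SD 1.89). TRP1, a tryptophan synthesis gene that also served as the disruption marker of GPD1, was called above the reference in 13 of 16 groups, with means from 0.23 to 3.12, the highest from 1 array. URA3, the uracil marker placed at GPD2, lay between -0.71 and 0.34, and LEU2, a leucine synthesis gene, between -1.02 and 0.36, both ends from 1 array. The strain list was not called at 20 min of erythritol (median -0.01, adjusted p = 0.285), 10 min of glycerol (0.09, 0.307), 60 min of sorbitol (-0.07, 0.777) or 30 min of xylitol (-0.01, 0.435). Positions of the probes relative to the disruptions are not given in the sources used here.

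Erythritol acted quickly. Within 20 min the cells raised genes for osmotic and general stress and storage sugars, and lowered those for making ribosomes and amino acids. Respiration genes rose as well, though much less with scan batch as a block. At 20 min 517 genes were called (257 up, 260 down; 1971 at an unadjusted p under 0.05), 206 with scan batch as a block and 246 without background correction. Among genes with the same sign on all 3 arrays the largest rises were CTT1, the cytosolic catalase (log2 5.37, SD 0.34), FMP48, a mitochondrial kinase gene (4.57, SD 0.17), STL1, a glycerol and proton symporter (4.41, SD 0.18), RTC3, an RNA metabolism gene raised in stress (3.87, SD 0.15), ALD3, an aldehyde dehydrogenase (3.78, SD 0.15), and NQM1, a transaldolase (3.67, SD 0.25). GRE2, a methylglyoxal reductase, rose by 3.04 and HSP12, a membrane-protecting heat shock protein, by 2.63. HOR7, a small osmotically induced membrane protein, rose by 2.16, GPP2, a glycerol 3-phosphatase, by 2.05 and its paralogue GPP1 by 1.18. The largest falls were YOR309C (-2.40, SD 0.30), the ribosome assembly genes MRT4 (-2.40, SD 0.07) and NOP15 (-2.33, SD 0.04), and OAC1, a mitochondrial oxaloacetate carrier (-2.16, SD 0.17).

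In the same group 19 of 22 osmostress genes were up, 19 as well when adjusted over the list alone (median 2.28, adjusted p = 7.06e-43; 2.38 with scan batch as a block). Of 26 Msn2/4 targets 21 were up (22 over the list alone; median 1.82, blocked 1.61), with SOL4, a phosphogluconolactonase, among the largest rises and the trehalose synthesis genes TSL1 at 3.20 and TPS2 at 3.06. The trehalose and glycogen list rose as well (12 of 19 up, 12 over the list alone, adjusted p = 8.98e-23, blocked median 1.41), with UGP1, which makes UDP-glucose, at 2.89 and PGM2, a phosphoglucomutase, at 2.42. Respiration genes rose by 0.72 (12 of 28 up, 12 over the list alone, blocked 0.13), including cytochrome c gene CYC1 (2.05). Heat shock genes rose by 0.78 (8 of 22, 8 over the list alone, blocked 0.48), including the disaggregase HSP104 (1.72) and BTN2, a protein-sorting factor (1.81). Glycerol metabolism genes rose by 0.56 (6 of 15, 6 over the list alone, blocked 1.01), including the dihydroxyacetone kinase DAK1 (1.75) and the glycerol dehydrogenase GCY1 (1.81). Ribosomal protein genes fell by 0.92 at the median (53 of 135 called, 54 over the list alone, blocked -0.75), with RPS27A at -1.82 and RPL23A at -1.61. Ribosome biogenesis genes fell by 1.08 (46 of 83, 46 over the list alone, blocked -0.79), with the nucleolar genes NHP2 (-2.10), NSR1 (-2.01) and CBF5 (-2.00). Gcn4 targets fell by 0.70 (6 of 26, blocked -0.32), led by the arginine gene ARG1 (-1.82). Phosphate genes fell by 0.70 (3 of 15 down and 1 up, blocked -0.48), led by the acid phosphatase PHO12 (-1.40). Each of these lists stayed called with an estimated correlation, the highest adjusted p being 0.0274.

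Glycerol raised part of the stress genes that erythritol raised, and its stress lists lay lower than in erythritol at 20 min. Of 54 genes called up at 20 min of glycerol, 52 were among the 257 called up at 20 min of erythritol. Catalase, STL1 and trehalose genes rose, and ribosomal protein genes fell by 20 min while ribosome biogenesis genes were not called as a list. At 10 min 175 genes were called (32 up, 143 down, and 1208 at an unadjusted p under 0.05). With scan batch as a block this group rests on replicate 3 alone, because replicates 1 and 2 shared a batch with no other group. Among genes with the same sign on all 3 arrays the largest rises were FMP48 (3.13, SD 1.11), CTT1 (2.67, SD 1.77) and STL1 (2.25, SD 1.04). They were followed by RTC3 (1.93, SD 0.40), YNL194C, a membrane protein gene (1.89, SD 1.06), and SOL4 (1.71, SD 0.37). The largest falls were CTR1, a copper transporter (-2.08, SD 1.91), UTP21, a ribosome assembly gene (-2.03, at least 3.02-fold lower because the treated channel was not above background), MKC7, a cell surface protease (-1.75, SD 2.28), and CSL4, an exosome subunit (-1.75, SD 1.85). GRE2 rose by 1.43 and GPP2 by 1.17, while HSP12 (0.70), GPP1 (0.63) and HOR7 (0.70) were not called. The count depended on single arrays, at 394 without replicate 1, 315 without replicate 2 and 30 without replicate 3. The split was 16 up and 1 down without background correction and 27 up and 8 down with print-tip loess. At 20 min 108 genes were called (54 up, 54 down, or 62 up and 16 down with print-tip loess), and 40 without replicate 2. With scan batch as a block 14 were left, and 41 without background correction. The rises included CTT1 at 2.28, GRE2 at 1.73, RTC3 at 1.57 and GPP2 at 1.07.

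Osmostress genes in glycerol rose by a median of 0.80 at 10 min (9 of 22 called, 9 over the list alone, blocked 1.11) and 1.03 at 20 min (10 called, 11 over the list alone, blocked 1.12). All blocked values at 10 min of glycerol rest on replicate 3 alone. Msn2/4 targets rose by 0.62 and 0.65 (5 and 7 called, 5 and 7 over the list alone, blocked 0.77 and 0.66). Trehalose genes rose by 0.50 and 0.52 (3 and 2 called, blocked 0.77 and 0.47), among them TSL1 (1.57 at 10 min) and GLC3, the glycogen branching enzyme (1.17). All of these stayed called with an estimated correlation (highest adjusted p = 0.0224). Ribosomal protein genes fell by 0.72 at 20 min (29 of 135 called, 29 over the list alone, adjusted p = 0.0137 with an estimated correlation, blocked -0.53), whereas ribosome biogenesis genes were not called as a list (median -0.06, adjusted p = 0.391, blocked 0.12). At 10 min the fall of ribosomal protein genes, led by RPS22B (-1.20), was smaller (-0.33, 3 called, adjusted p = 0.40 with an estimated correlation, blocked 0.08). Ribosome biogenesis genes at 10 min lay at -0.24 (6 called, 7 over the list alone, adjusted p = 0.41 with an estimated correlation, blocked -0.41). The glycerol metabolism list lay at 0.30 (2 up and 1 down, the aquaporin AQY2 at -1.09, adjusted p = 0.127 with an estimated correlation, blocked 0.05). Heat shock genes were not called as a list (0.04, adjusted p = 0.127), and Gcn4 targets fell by 0.53 at 20 min (1 called, blocked -0.28).

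Xylitol acted on many of the same lists as erythritol. After 30 min stress, storage sugar and respiration genes rose, and ribosome and amino acid genes fell. At 30 min 395 genes were called (198 up, 197 down, or 129 up and 68 down without background correction; 2072 at an unadjusted p under 0.05), and 213 without replicate 3. Among genes with the same sign on all 3 arrays the largest rises were RTC3 (3.71, SD 0.28), YGR051C (3.54, SD 0.27), SOL4 (3.46, SD 0.33), FMP48 (3.24, SD 0.69), YNL194C (3.07, SD 0.69) and FMP16, a mitochondrial stress gene (2.94, SD 0.60). STL1 rose by 3.24, GRE2 by 3.51, HSP12 by 2.97, GPP2 by 2.08 and HOR7 by 1.93, while CTT1 (5.21) and GPP1 (1.82) rested on 1 array each. Falls were led by FTR1, the iron permease (-2.09, SD 0.14), ELO3, a fatty acid elongase (-1.94, SD 0.97), the RNA polymerase I subunit RPA34 (-1.91, SD 1.51) and UTP8, a nucleolar gene (-1.91, SD 1.37).

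In xylitol 19 of 22 osmostress genes were up (19 over the list alone; median 2.13, blocked 1.97), with ALD3 at 4.29 on 2 arrays. So were 18 of 26 Msn2/4 targets (18 over the list alone; 1.77, blocked 1.23). Trehalose and glycogen genes rose by 0.90 (7 of 19, blocked 0.85), with TSL1 at 2.61 and UGP1 at 2.35. Glycerol metabolism genes rose by 0.84 (7 up, 1 down, blocked 0.71), respiration genes by 0.70 (6 up, blocked 1.02), with QCR10 of the cytochrome bc1 complex at 1.45. Heat shock genes rose by 0.59 (6 up, blocked 0.51), with HSP104 at 1.61. Ribosomal protein genes fell by 0.85 (43 of 135, 45 over the list alone, blocked -0.72), with RPS12 at -1.69 and RPS7B at -1.55. Ribosome biogenesis genes fell by 0.69 (27 of 83, 27 over the list alone, blocked -0.64), with CBF5 at -1.60. Gcn4 targets fell by 0.56 (6 of 26, blocked -0.72), phosphate genes by 0.63 (1 down and 1 up, 2 and 1 over the list alone, blocked -0.67) and G1/S genes by 0.29 (2 of 16, blocked -0.21), with SPT21, a histone gene regulator, at -1.04. All of these stayed called with an estimated correlation (highest adjusted p = 0.0375). Iron genes lay at -0.79 (5 down, including the siderophore transporter ENB1 at -1.57, adjusted p = 0.074 with an estimated correlation, blocked -0.85).

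Sorbitol acted late. Few genes were called up to 20 min, where 2 of 3 arrays at 10 min and 1 of 2 at 20 min were weak, and osmostress genes had risen by 20 min. At 60 min stress genes were up and ribosomal protein, amino acid and iron genes down. At 60 min 442 genes were called (185 up, 257 down, or 52 up and 45 down without background correction; 2088 at an unadjusted p under 0.05). The count was 823 when the weak replicate 2 was left out and 251 without replicate 3. Among genes with the same sign on all 3 arrays the largest rises were RTC3 (3.74, SD 0.89), SIP18, a desiccation protein gene (3.66, SD 2.45, at least 11-fold because the reference was not above background), and SOL4 (3.09, SD 0.74). They were followed by GRE2 (3.08, SD 1.10), SPS100, a spore wall gene (3.02, at least 5.69-fold), and HEL2, a ribosome quality control ligase (2.84, SD 0.18). Measured on only 2 arrays, CTT1 (4.66) and ALD3 (4.19) stood higher still. Falls were led by GDH1, a glutamate dehydrogenase (-2.39, SD 1.38), ARG3, an arginine synthesis gene (-2.14, SD 1.90), TIS11, which degrades mRNA when iron is short (-2.03, SD 1.84), and ILV5, a branched-chain amino acid gene (-1.98, SD 0.29). STL1 stood at 2.70 (at least 5.38-fold), HSP12 at 2.54, HOR7 at 2.38, GPP2 at 1.76 and GPP1 at 1.26.

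At 60 min of sorbitol 19 of 22 osmostress genes were up (19 over the list alone; median 2.23, blocked 1.93), as were 15 of 26 Msn2/4 targets (15 over the list alone; 1.20, blocked 0.84), with DDR2, a multistress gene, at 2.40. Ribosomal protein genes fell by 1.20 (87 of 135, 87 over the list alone, blocked -1.14), with RPL37A at -1.94 and RPS27B at -1.81. Gcn4 targets fell by 0.78 (10 of 26, 10 over the list alone, blocked -0.95), with ARG1 at -1.94 and TRP4, a tryptophan gene, at -1.85. Iron genes fell by 1.09 (8 of 16, 8 over the list alone, blocked -1.01), with FTR1 at -1.93, the siderophore transporter ARN1 at -1.54 and the ferroxidase FET3 at -1.49. Phosphate genes fell by 0.92 (4 down and 1 up, 5 and 1 over the list alone, blocked -0.97). These lists stayed called with an estimated correlation (highest adjusted p = 0.0254). Ribosome biogenesis genes lay at -0.67 (18 of 83, 19 over the list alone, blocked -0.59), with CBF5 at -1.89. Respiration genes lay at 0.66 (6 up, blocked 0.84) and heat shock at 0.62 (4 up, blocked 0.57), all 3 lists with an adjusted p = 0.0539 with an estimated correlation. Trehalose genes lay at 0.36 (4 up, including TSL1 at 2.03, adjusted p = 0.0611 with an estimated correlation, blocked 0.41) and glycerol metabolism genes at 0.18 (6 up, adjusted p = 0.0607 with an estimated correlation, blocked 0.24).

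Lists with smaller shifts completed the picture at each polyol's time with most calls. The sorbitol and xylitol list lay at 0.21 in erythritol (2 up, adjusted p = 0.106 with an estimated correlation, blocked 0.55), where GRE3, the aldose reductase, rose by 2.08 and XKS1, the xylulokinase, by 1.15. It was not called in xylitol (0.02, adjusted p = 0.311) or sorbitol (0.03, 0.0562), although GRE3 rose by 1.72 and 2.13. Oxidative stress genes lay at 0.42 in erythritol, 0.32 in xylitol and 0.43 in sorbitol (adjusted p = 0.249, 0.137 and 0.132 with an estimated correlation, blocked 0.07, 0.20 and 0.39), with PRX1, a mitochondrial peroxiredoxin, at 1.92, 1.67 and 1.76. Ergosterol genes lay at -0.30, -0.40 and -0.57 (adjusted p = 0.234, 0.137 and 0.119 with an estimated correlation, blocked -0.42, -0.36 and -0.58), with the desaturase ERG3 at -1.22, -1.41 and -1.09. Iron genes in erythritol lay at -0.36 (2 down, adjusted p = 0.264 with an estimated correlation, blocked 0.10). The M/G1 list, with the daughter-cell repressor ASH1 at -1.05 in xylitol, lay at -0.26 there and -0.42 in sorbitol (adjusted p = 0.196 and 0.0814 with an estimated correlation, blocked -0.31 and -0.52). Proteasome genes lay at 0.22 in xylitol and 0.27 in sorbitol (adjusted p = 0.263 and 0.224 with an estimated correlation), with their activator RPN4 at 1.25 and 1.26, and glycolysis genes at -0.38 in sorbitol (2 down, adjusted p = 0.127 with an estimated correlation, blocked -0.49). Cell wall genes were not called as a list in erythritol, xylitol or sorbitol (adjusted p = 0.796, 0.155 and 0.543), although the mannoprotein gene CWP1 rose by 1.76, 1.23 and 1.07. Mating genes were not called as a list (adjusted p = 0.252, 0.153 and 0.864), though MFA2, an a-factor gene, fell to -1.95, -1.21 and -1.12. Histone genes (0.655, 0.259 and 0.426), G2/M genes (0.622, 0.0686 and 0.495) and hexose transporters (0.285, 0.435 and 0.36) were not called as lists, while the transporter HXT5 rose by 1.54, 2.04 and 1.91.

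Erythritol and xylitol had raised osmostress genes before their times with most calls. Erythritol had 63 genes called at 5 min (37 up, 26 down, or 9 and 2 without background correction and 32 and 10 with print-tip loess) and 36, 36 and 40 without replicate 1, 2 or 3. At 10 min it had 309 (135 up, 174 down, or 83 and 28 without background correction and 112 and 32 with print-tip loess) and 196 without replicate 3. Osmostress genes lay at 0.43 and 1.53 at these times (5 and 14 called and as many over the list alone, blocked 0.74 and 1.54), and STL1 reached 3.41 and RTC3 3.00 at 10 min. Xylitol had 10 genes called at 5 min (8 up, 2 down, or 8 and 6 without background correction), a count that fell to 0 with limma and scan batch as a block, and 19 at 10 min (18 up, 1 down), where the count was 11 without replicate 1 and 8 with scan batch as a block. At 20 min it had 202 (106 up, 96 down, or 109 and 47 with print-tip loess), 115 without replicate 1 and 45 with scan batch as a block. Its osmostress list lay at 0.72 at 10 min (6 called, 7 over the list alone, blocked 0.48) and 1.59 at 20 min (13 called, 16 over the list alone, blocked 1.25), with STL1 at 2.17 and 3.39.

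Glycerol at 5 min and sorbitol up to 20 min had few genes called. At an unadjusted p under 0.05 sorbitol had 1179 genes at 5 min, 821 at 10 min and 812 at 20 min. At 5 min glycerol had 472 such genes and erythritol 1116. With no limit on the log2, 93 genes were called at 5 min of sorbitol and 11 at 5 min of glycerol. Glycerol had 8 genes called at 5 min (6 up, 2 down, or 7 and 0 with print-tip loess) and 4, 2 and 0 without replicate 1, 2 or 3, while osmostress genes lay at 0.45 (1 called, 4 over the list alone, blocked 0.72) and ribosomal protein genes at -0.48 (2 called, 5 over the list alone, blocked -0.37). Sorbitol had 21 genes called at 5 min (4 up, 17 down, or 1 and 2 without background correction) and 0, 5 and 0 without replicate 1, 2 or 3. With limma that count was also 0 with print-tip loess and with scan batch as a block. At 10 min it had 16 (3 up, 13 down, or 9 and 4 with print-tip loess) and 213, 79 and 3 without replicate 1, 2 or 3, of which replicates 1 and 3 were weak, and 4 with scan batch as a block. At 20 min it had 61 (36 up, 25 down), 99 without replicate 1, 26 without the weak replicate 2, 7 without background correction and 1 with scan batch as a block. Leaving out an array there leaves 1, and so does the block for scan batch, which rests on the weak replicate 2. The spread then comes from the other groups. Osmostress genes were not called as a list at 5 and 10 min of sorbitol (median 0.11 at both, adjusted p = 0.258 and 0.353) and lay at 0.72 at 20 min (8 called, 10 over the list alone, blocked 0.96). Sorbitol at 30 min had 329 genes called (163 up, 166 down, or 56 and 123 without background correction) and 564 without the weak replicate 1, and 128 with scan batch as a block. At 90 min it had 394 (184 up, 210 down, or 167 and 80 with print-tip loess) and 177 without replicate 1. Osmostress genes lay at 1.66 and 2.24 at 30 and 90 min (19 called at both, 19 and 20 over the list alone, blocked 1.45 and 2.14), with CTT1 at 4.95 and at least 39.0-fold up, and ribosomal protein genes at -0.85 at both (blocked -0.58 at 30 min, and lower still at 90 min).

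Over time the answers to erythritol, xylitol and sorbitol built up, while for glycerol the test of single genes depended on single arrays. With the batch as a block the counts of changed genes were 69 for erythritol and 81 for xylitol. The block left only replicate 1 at 5 min and replicate 3 at 10 min of glycerol. At 20 min of sorbitol it left the weak replicate 2. Blocked counts for glycerol and sorbitol are therefore not read as results. In erythritol 54 genes changed (618 at an unadjusted p under 0.05; 92 without background correction, 82 with print-tip loess), with STL1 spanning 4.13 (adjusted p = 0.0114), SIP18 3.24, CTT1 2.84, NQM1 2.79 and SPG1, a stationary phase gene, 2.73, all lowest at 5 min and highest at 20 min, although STL1 at 5 min was not above background in either channel. CTT1 went from 2.54 to 4.62 and 5.37. The osmostress difference between 20 and 5 min was 1.75, 1.53 and 2.02 inside the 3 scan batches that held both times (pooled 1.69). The erythritol count fell to 17, 23 and 33 when replicate 1, 2 or 3 at 5 min was left out, and to 16, 21 and 19 when replicate 1, 2 or 3 at 20 min was. In xylitol 57 genes changed (574 at an unadjusted p under 0.05; 230 without background correction, 117 with print-tip loess), led by ALD3 (3.26), NQM1 (3.17), SIP18 (3.12), YGR051C (3.01) and FMP16 (2.72). This count was 25 without replicate 2 at 5 min, 109 without replicate 2 at 20 min and 25 without replicate 3 at 30 min. Within scan batches the osmostress list rose by 1.28 and 1.75 between 5 and 30 min of xylitol. In sorbitol 459 genes changed (1350 at an unadjusted p under 0.05), with CTT1 spanning 4.64, ALD3 4.02, NQM1 3.98 and SIP18 3.64 (SIP18 not above background at its lowest time), and the osmostress list rose by 2.14 between 5 and 90 min within 1 scan batch. STL1 also changed over the sorbitol times (adjusted p = 0.000238), from 5 min where it was not above background in the treated channel. The limma test found 0 genes over the glycerol times (200 at an unadjusted p under 0.05), where CTT1 spanned 1.51, RTC3 0.87 and STL1 0.35. That count was 23 and 3 when replicate 1 or 2 at 10 min was left out. The osmostress medians of glycerol climbed from 0.45 to 0.80 and 1.03 (blocked 0.72, 1.11 and 1.12), and no scan batch held more than 1 of these times.

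**Figure D1:**
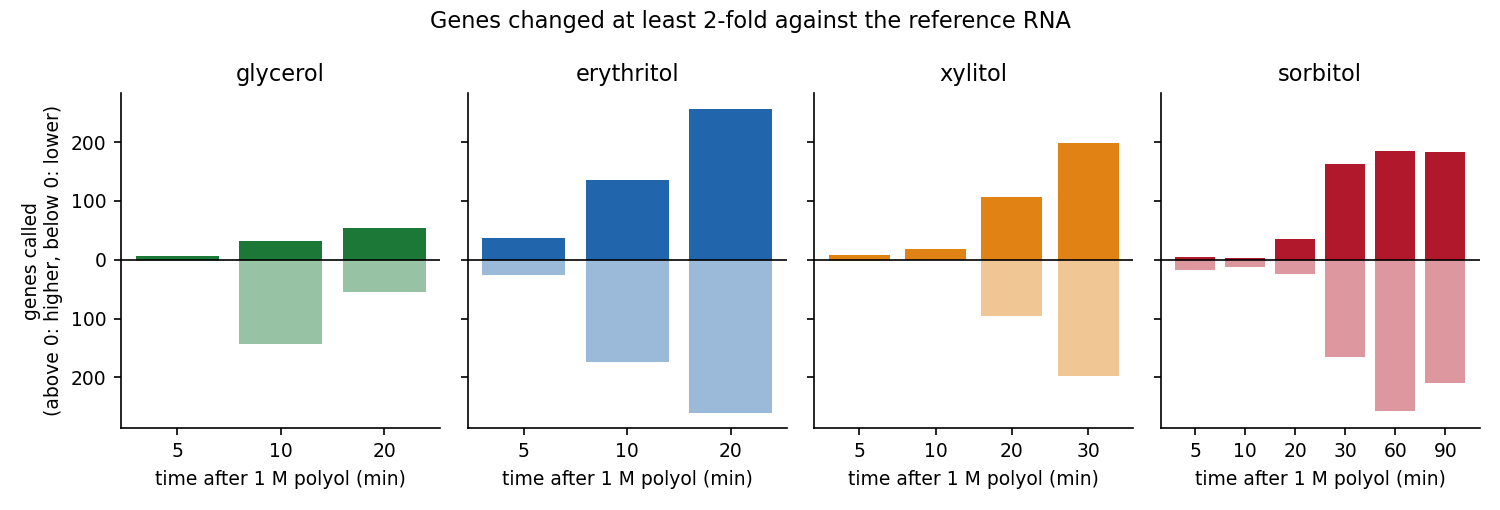
Number of genes called against the reference at each time (min), with genes up above 0 and genes down below 0, in 1 panel per polyol. Sorbitol bars are short up to 20 min and long from 30 min.

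**Figure D2:**
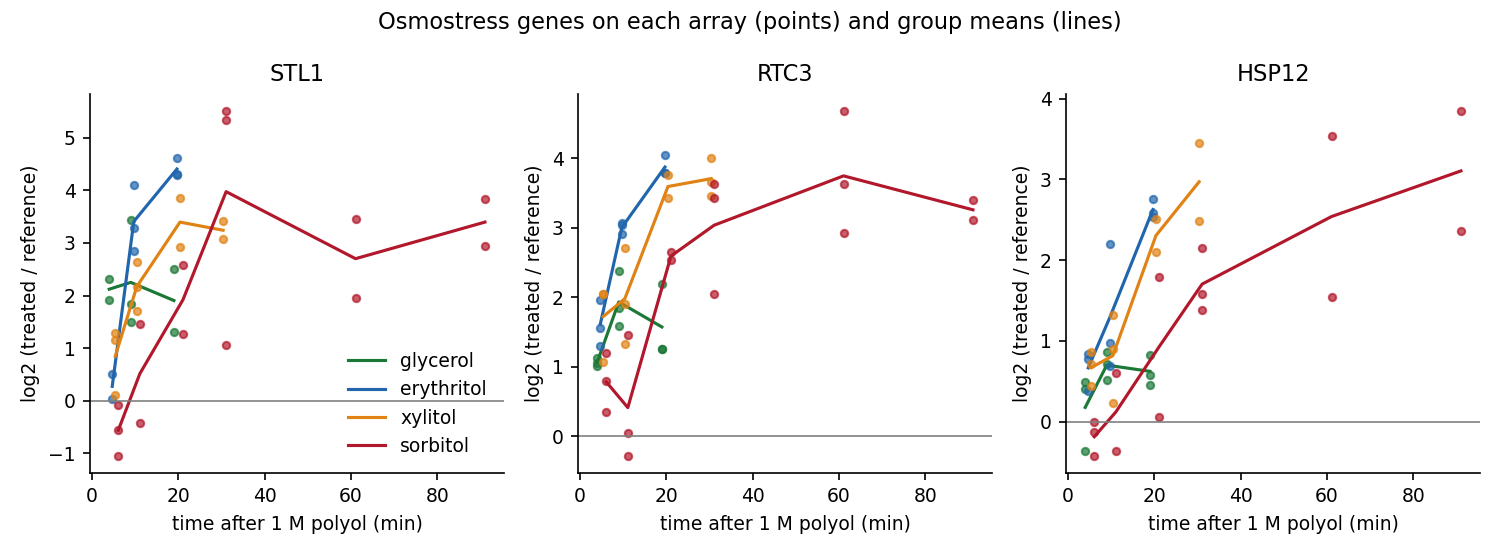
log2 ratio of STL1, RTC3 and HSP12 against time (min) for each polyol, with points for arrays and lines for group means. Many STL1 values were not above background in the reference. At 20 min the group mean of glycerol was the lowest for RTC3 and HSP12, although sorbitol replicate 1 lay lower still for HSP12 (0.06).

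**Figure D3:**
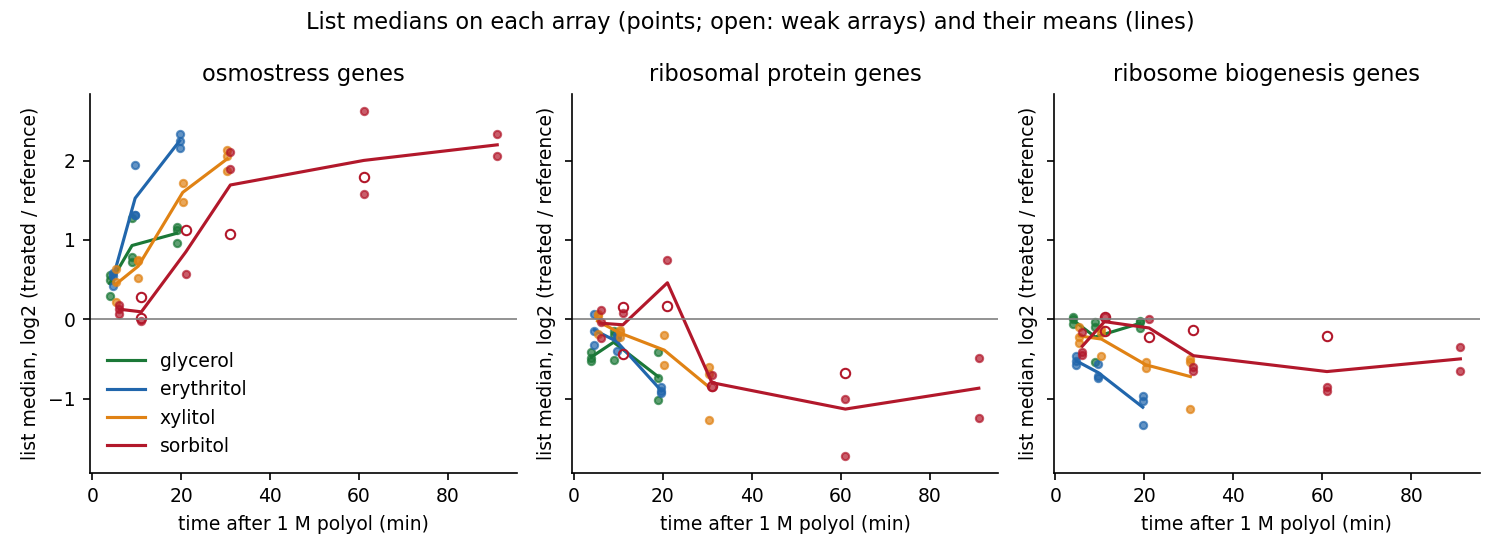
Median log2 ratio of the osmostress, ribosomal protein and ribosome biogenesis lists against time (min), with points for arrays, open points for weak arrays and lines for means over arrays. Osmostress medians climb in erythritol and xylitol, later in sorbitol, and less steeply in glycerol.

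Erythritol and glycerol had parted by 20 min. After 20 min the larger molecule had raised stress and trehalose genes further and lowered ribosome biogenesis genes that were not called as a list in glycerol, and ribosomal protein genes fell in both. Between erythritol and glycerol at 20 min 135 genes differed (58 higher and 77 lower in erythritol, and 700 at an unadjusted p under 0.05). The shared scan batch held 3 glycerol arrays but only 1 erythritol array at this time. CTT1 was higher by 3.09 (95% interval 2.04 to 4.15, and 3.46 within the shared scan batch), UGP1 by 2.43 (1.78 to 3.07, batch 2.26), SPI1, a cell wall stress gene, by 2.41 (1.53 to 3.29, batch 2.29), RTC3 by 2.30 (1.48 to 3.12, batch 2.22) and HSP12 by 2.00 (1.12 to 2.88). NOP15 was lower at -2.49 (-3.24 to -1.74, batch -2.47), MRT4 at -2.25 (-3.06 to -1.45, batch -2.21) and CGR1, a ribosome assembly gene, at -2.00 (-2.78 to -1.22, batch -2.12, at least 1.96-fold lower). Without background correction CGR1 (-0.89), and with print-tip loess HSP12 (0.56), were not called. STL1 (2.50, 0.89 to 4.11) was not called. The count was 34, 68 and 84 when replicate 1, 2 or 3 of erythritol was left out, and 87, 55 and 39 when replicate 1, 2 or 3 of glycerol was. With scan batch as a block it was 58, and with print-tip loess 224.

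As lists at 20 min, osmostress genes were higher in erythritol by 1.31 (7 genes, 15 over the list alone, within the batch 1.45, and nearly the same with scan batch as a block), Msn2/4 targets by 1.31 (12 genes, 19 over the list alone, blocked 1.04, within the batch 1.31) and trehalose genes by 0.90 (6 genes, 11 over the list alone, blocked 1.06, within the batch 0.80). Ribosome biogenesis genes were lower at -0.97 (29 genes, 47 over the list alone, blocked -0.92, within the batch -0.85), and the ribosomal protein lists lay close at -0.12 (adjusted p = 0.628 with an estimated correlation, blocked -0.15, within the batch -0.19). Heat shock genes were higher by 0.69 and respiration genes by 0.52 (blocked 0.65 and 0.71), each called with an estimated correlation. Values within the batch rest on 1 erythritol array at each time, and at 5 min also on 1 glycerol array. Ribosome biogenesis genes lay lower in erythritol already at 5 min (-0.45, within the batch -0.37), while osmostress genes lay close (0.03). By 10 min osmostress genes lay at 0.54 and Msn2/4 targets at 0.59 (within the batch 0.52 and 0.37). Ribosome biogenesis genes then lay at -0.41, but at -0.02 within the batch. At 5 and 10 min the limma test found 0 genes between erythritol and glycerol (327 and 320 at an unadjusted p under 0.05). CTT1 differed by 1.38 (0.32 to 2.44, within the batch 0.97) and 1.95 (0.89 to 3.01, within the batch 0.37), neither called, and STL1 at 10 min by 1.15 (-0.28 to 2.59, within the batch 0.66). At 5 min STL1 lay the other way, lower in erythritol at -1.84 (within the batch -1.40), and was not called. The counts were 1 without replicate 2 of erythritol at 5 min and 3, 2 and 5 without replicate 1, 2 or 3 of glycerol at 10 min. With scan batch as a block, and within the batch, 10 min of glycerol rests on replicate 3 alone. The blocked count is therefore not read as a result.

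Sorbitol and glycerol, which differ most in size, gave counts of differing genes that depended on single arrays. With the batch as a block, 10 min of glycerol rested on replicate 3 alone and 20 min of sorbitol on the weak replicate 2. The values within the batch at 10 min rested on the same glycerol array, so the blocked counts are not read as results. Glycerol had raised osmostress genes by 10 min when sorbitol had not. At 5 min the limma test found 0 genes (328 at an unadjusted p under 0.05), with STL1 at least 4.68-fold lower in sorbitol, where it was not above background, and not called (adjusted p = 0.873). At 10 min it found 1 gene (722), UTP21, higher in sorbitol by 1.90 (1.18 to 2.63, at least 1.91-fold, blocked 2.59, within the batch 2.84). UTP21 was not called without background correction (0.45) or with print-tip loess (0.80). It lay at 1.55 without the weak arrays, where 1 sorbitol array was left. CTT1 at -2.02 (-3.08 to -0.97, within the batch -4.06, adjusted p = 0.099) was not called. The count was 0 with limma both without background correction and without the dimmest genes, and it became 107, 65 and 2 without replicate 1, 2 or 3 of glycerol, and 58 and 33 without replicate 1 or 2 of sorbitol. The osmostress list at 10 min lay at -0.70 (0 genes called by limma, 6 down over the list alone, adjusted p = 0.0444 with an estimated correlation, blocked -1.01, within the batch -1.25). At 20 min 18 genes were higher in sorbitol (48 up and 11 down with print-tip loess, and 498 at an unadjusted p under 0.05), among them RPS7A (2.05, 1.08 to 3.03), ASC1, a ribosome-bound signalling protein (1.79, 1.09 to 2.49), and RPL23A (1.68, 1.03 to 2.33). With scan batch as a block RPS7A lay at 1.16 and ASC1 at 1.07, and RPL23A was not called with print-tip loess (0.79). RPL9A (2.35) and RPS4B (1.70) rested on 1 sorbitol array each. Ribosomal protein genes lay 1.15 higher (16 genes, 105 over the list alone, adjusted p = 0.00218 with an estimated correlation), but 0.26 with scan batch as a block, and no batch held both groups. Leaving out replicate 1 or 2 of glycerol gave 2 and 0 genes and leaving out replicate 1 or 2 of sorbitol, the second a weak array, 3 and 63. STL1 (0.01, -1.74 to 1.77) and CTT1 (0.25, -0.93 to 1.44) were not called. Of the sorbitol arrays, 2 of 3 at 10 min and 1 of 2 at 20 min were weak.

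Xylitol and erythritol, neighbours in size, differed in few single genes in the fit without batches. Erythritol led in osmostress and trehalose genes at 10 min. With scan batch as a block 21 genes differed at 5 min and 96 at 10 min (68 higher, 28 lower in xylitol). The limma test found 0 genes at 5 and 10 min (362 and 501 at an unadjusted p under 0.05) and 4 at 20 min (409). At 20 min GLN1, the glutamine synthetase, was higher in xylitol (1.52, 0.97 to 2.06, blocked 1.18), and NCE103, the carbonic anhydrase (-2.18, adjusted p = 0.00744, blocked 0.06), was lower. YML119W (-2.32, blocked -1.62) and YFR006W (-2.57, blocked -0.94) were lower on the 1 xylitol array that measured each. Without background correction the split was 9 up and 79 down, and the count was 0 and 53 without replicate 1 or 2 of xylitol. Leaving out replicate 2 of erythritol gave 1 gene at 5 min and 4 at 10 min, and replicate 1 of xylitol 1 gene at 5 min. Osmostress genes lay at -0.74 at 10 min (0 genes called by limma, 8 down over the list alone, blocked -1.26, within the batch -1.58) and trehalose genes at -0.46 (7 down over the list alone, blocked -1.03, within the batch -0.86), both with an adjusted p = 0.0218 with an estimated correlation. Between the single xylitol and erythritol arrays of the shared batch CTT1 lay at -2.69, STL1 at -2.39, SPI1 at -2.08, GRE2 at -2.00 and HSP12 at -1.97. At 20 min STL1 (-1.01, -2.62 to 0.60) and RTC3 (-0.28, -1.19 to 0.64) were not called, and osmostress genes lay lower in xylitol (-0.59, adjusted p = 0.172 with an estimated correlation, blocked -1.16).

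Sorbitol lay below xylitol in osmostress genes, by -0.65 at 10 min, -0.61 at 20 min and -0.62 at 30 min (adjusted p = 0.154, 0.128 and 0.144 with an estimated correlation, blocked -0.61, -0.37 and -0.55). Msn2/4 targets stayed lower in sorbitol at 20 and 30 min. At these 3 times 4 of the sorbitol arrays were weak. With scan batch as a block, 20 min of sorbitol rests on the weak replicate 2 alone. The limma test found 0 genes at 5 min (397 at an unadjusted p under 0.05), 2 at 10 min (544), 6 at 20 min (550) and 0 at 30 min (659). With scan batch as a block 5 genes were found at 10 min and all 6 calls at 20 min were lost. At 30 min the count was 75 without the weak arrays and 95 without background correction. At 10 and 20 min leaving out the weak arrays left 1 sorbitol array, so the counts there are not read as results. At 10 min PRM10, a pheromone-regulated membrane protein (-2.00, -2.77 to -1.24, within the batch -1.44), and YCLX03C (at least 1.10-fold, not above background in sorbitol) were lower in sorbitol, neither of them called with poor-flagged spots kept (-1.84 and -1.75), with a split of 3 up and 8 down with print-tip loess. At 20 min ORC3, an origin recognition subunit (2.16, 1.35 to 2.97, blocked 0.87), was higher. YML119W (2.64, blocked 2.05) and YFR006W (at least 1.70-fold, not above background in sorbitol) were higher against 1 xylitol array each. PHM8, a nucleotide phosphatase (-1.74, -2.50 to -0.99, blocked -1.69), was lower. The split was 21 up and 1 down without background correction and 17 up and 19 down with print-tip loess. Msn2/4 targets lay at -1.14 at 20 min (18 down over the list alone, adjusted p = 0.00492 with an estimated correlation, blocked -0.63) and -0.76 at 30 min (11 down, adjusted p = 0.0386 with an estimated correlation, blocked -0.59, within the batch -0.48). Trehalose genes lay at -0.75 at 20 min (7 down, adjusted p = 0.00492 with an estimated correlation, blocked -0.53). At 30 min STL1 (0.73, -0.88 to 2.34), CTT1 (-0.26, -1.75 to 1.24, 1 xylitol array) and RTC3 (-0.67, -1.49 to 0.15) were not called. Without replicate 1, 2 or 3 of sorbitol the counts were 49, 19 and 1 at 10 min and 25, 4 and 8 at 30 min. Without replicate 1 or 2 of sorbitol they were 2 and 25 at 20 min. Without replicate 1, 2 or 3 of xylitol the count was 1, 0 and 1 at 10 min. Without replicate 1 or 2 it was 0 and 30 at 20 min, without replicate 2 or 3 it was 5 and 14 at 30 min, and without replicate 1 it was 1 at 5 min.

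No single gene passed the limma test for a different change over time between polyols. With 2 or 3 arrays per group, a count of 0 does not show equal courses. The count was 0 in all 5 tests, with 200 genes for sorbitol and glycerol between 5 and 20 min at an unadjusted p under 0.05, 224 for erythritol and glycerol, 150 for xylitol and erythritol, 353 for sorbitol and xylitol, and 391 for sorbitol and xylitol between 5 and 30 min. STL1, which was not above background at 5 min of erythritol or sorbitol, was called in none of them. Its estimates in the same order were 2.69, 4.34, -1.58, -0.07 and 2.13.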

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

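The tests without weak arrays, of sorbitol arrays at 5 min and of the sorbitol rise inside scan batches were chosen after the result was seen. Between polyols 1, 18, 135, 4, 2 and 6 genes differed for sorbitol minus glycerol at 10 and 20 min, erythritol minus glycerol at 20 min, xylitol minus erythritol at 20 min, and sorbitol minus xylitol at 10 and 20 min. Over time 54 genes changed in erythritol, 459 in sorbitol and 57 in xylitol.

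For erythritol over time 1 of 100 splits of the arrays, the real one, gave as many as 54 genes, and the highest other gave 28. This makes chance unlikely but does not exclude it, and the splits took no account of scan batch. For glycerol over time all 100 splits gave as many as the real 0, and the highest other gave 2. For 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. For erythritol minus glycerol at 20 min the real split gave 135 and the highest other 0, which was 1 of 10 splits. At 5 min the real value was 0 and the highest other 1, and at 10 min 0 and 134. Sorbitol minus glycerol gave 0 and 0 at 5 min and 1 and 181 at 10 min, where 6 of 10 splits gave as many. Xylitol minus erythritol gave 0 and 5 at 5 min and 0 and 2 at 10 min. Sorbitol minus xylitol gave 0 and 1 at 5 min, 2 and 12 at 10 min, where 4 of 10 splits gave as many, and 0 and 87 at 30 min.

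Other splits with many genes point to structure between arrays. The split with 134 genes set replicates 1 and 3 of erythritol at 10 min with replicate 3 of glycerol against the others, and both replicates 3 were scanned in batch 11. The split with 87 genes at 30 min of sorbitol and xylitol set the arrays of batch 11 against the others. The split with 181 genes set replicates 1 and 2 of sorbitol at 10 min, the first of them weak, with replicate 3 of glycerol.

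In glycerol ribosomal protein genes fell at 20 min while ribosome biogenesis genes were not called as a list. Genes nearest in mean intensity had a median of -0.05, at the lowest -0.22 over 1000 draws, against -0.72 for ribosomal protein genes. The loess pulls the typical ratio at each intensity towards 0, so this outcome was largely fixed in advance. It does not exclude brightness of the ribosomal protein spots. In the contrast with erythritol, ribosome biogenesis genes lay at -0.92 with the batch as a block and at -0.85 within the shared batch. That batch held only 1 erythritol array at 20 min, so a difference between scan batches is not excluded. These values of -0.05 and -0.92 do not compare the 2 sets of genes with each other in glycerol, and that difference was not tested. On the 3 arrays at 20 min the ribosomal protein medians were -0.74, -1.02 and -0.41. The ribosome biogenesis medians there were -0.11, -0.03 and -0.02. All 3 arrays were in the same scan batch, so a part of the batch in the fall itself cannot be told apart.

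Few genes were called in sorbitol up to 20 min. Weak arrays are excluded as the cause at 5 min, where none of the 3 arrays was weak and osmostress medians were at most 0.18, against at least 1.07 on every array from 30 min on. A difference between scan batches is excluded as the cause of the gap between the times up to 10 min and from 30 min, because the list rose by at least 1.24 inside each of 3 batches. Weak arrays could still have a part at 10 and 20 min, where the list lay at -0.74 in sorbitol minus xylitol without them but 1 sorbitol array was left at each time. Scan batch could still have a part in that difference. With the batch as a block it was -0.61 at 10 min (adjusted p = 4.19e-05 by cameraPR) and -0.37 at 20 min. At 20 min the block rests on the weak replicate 2 of sorbitol alone, so it cannot separate scan batch from weak signal.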

How the results depend on the processing

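The weak-array and poor-spot tests were chosen after the result was seen, as was the rule for using a column of the deposited table. A value is given as reversed when a result called in the fit described here changed sign, for a list the sign of its median; this wording was narrowed after a first version with 36 such values had been seen. Of all gene and list values 29 were reversed, 25 of lists and 4 of genes, including those from leaving out 1 array. Of the counts of 35 results, 99 moved by more than 1.5 times under the other settings, and 77 more when 1 array was left out. The planned tests with only the first or only the second scan were not run, because the files of an array are its channels.

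Without background correction the counts against the reference were 11 at 5 min, 111 at 10 min and 246 at 20 min of erythritol, 3, 17 and 41 at the same times of glycerol, 3, 0, 7, 179, 97 and 133 over the sorbitol times and 197 at 30 min of xylitol. Sorbitol minus glycerol gave 0 genes at 10 min and 42 at 20 min, and xylitol minus erythritol 88 at 20 min. Sorbitol minus xylitol gave 5, 1, 22 and 95 genes at 5, 10, 20 and 30 min, and the time tests 92 for erythritol and 230 for xylitol. Genes rose in a larger share at 5 min of erythritol (9 up and 2 down against 37 and 26), at 10 min (83 and 28 against 135 and 174) and in a smaller share at 30 min of sorbitol (56 and 123 against 163 and 166). Splits were 1 and 2 at 5 min of sorbitol against 4 and 17, and 8 and 6 at 5 min of xylitol against 8 and 2. UTP21 in sorbitol minus glycerol at 10 min lay at 0.45 and CGR1 in erythritol minus glycerol at -0.89, and neither was called. Of 1320 gene and list values 1146 were the same, 38 stronger, 136 weaker and 0 reversed.

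With print-tip loess the counts were 144 at 10 min of erythritol, 35 at 10 min of glycerol, and 0 at 5 min and 247 at 90 min of sorbitol. The differences gave 5 and 59 genes for sorbitol minus glycerol at 10 and 20 min, 224 for erythritol minus glycerol at 20 min, 15 for xylitol minus erythritol at 20 min, and 11, 36 and 1 for sorbitol minus xylitol at 10, 20 and 30 min. The time tests gave 82 for erythritol and 117 for xylitol. Splits were 32 up and 10 down at 5 min and 112 and 32 at 10 min of erythritol, 7 and 0 at 5 min of glycerol against 6 and 2, 9 and 4 at 10 min of sorbitol against 3 and 13, 167 and 80 at 90 min against 184 and 210, 109 and 47 at 20 min of xylitol against 106 and 96, and 1 and 4 for sorbitol minus glycerol at 10 min. Glycolysis at 20 min of sorbitol went from -0.25 to 0.05 and TDH1 at 60 min from -1.11 to 0.03. Of all values 1189 were the same, 33 stronger, 96 weaker and 2 reversed.

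Leaving out the dimmest 25% of genes gave 93 genes at 10 min of glycerol, 1 at 10 min of sorbitol, 0 and 57 for sorbitol minus glycerol at 10 and 20 min, and 1 each for sorbitol minus xylitol at 10 and 30 min. Of 1268 values 1230 were the same and 0 reversed. With no limit on the log2 the counts were 144, 863 and 1290 in erythritol, 357 at 10 min and 304 at 20 min in glycerol, 93, 25, 985, 1278 and 731 at 5, 10, 30, 60 and 90 min in sorbitol and 32, 319 and 1264 at 10, 20 and 30 min in xylitol. This call rule left 1304 values the same, 16 stronger and 0 reversed.

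Scans fell into 11 batches of 1 to 9 arrays, of which 8 held more than 1 group, and 5193 of 6293 genes could be fitted with the batch as a block. The counts became 206 at 20 min of erythritol, 416 at 10 min and 14 at 20 min of glycerol, 0, 4, 1 and 128 at 5, 10, 20 and 30 min of sorbitol and 0, 8 and 45 at 5, 10 and 20 min of xylitol. Differences became 4, 408 and 0 for sorbitol minus glycerol, 1, 193 and 58 for erythritol minus glycerol at 5, 10 and 20 min, 21 and 96 for xylitol minus erythritol at 5 and 10 min, and 5 and 0 for sorbitol minus xylitol at 10 and 20 min. The time test of glycerol gave 59, and 65 list differences between polyols were called instead of 101. The block rests on 1 array at 5 and 10 min of glycerol and at 20 min of sorbitol. Counts that involve these groups, in differences and time tests too, are listed for completeness and are not read as batch-adjusted results. Of 1225 values 971 were the same, 56 stronger, 179 weaker and 19 reversed.

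Reversed with the scan batch as a block were ribosomal proteins at 5 min of erythritol (-0.10 to 0.06), 10 min of glycerol (-0.33 to 0.08) and 20 min of sorbitol (0.36 to -0.20), and in xylitol minus erythritol at 10 min (0.14 to 0.00). Respiration turned at 5 min (0.46 to -0.18) and 10 min (0.28 to -0.01) of erythritol, at 20 min of glycerol (0.22 to -0.57), and in xylitol minus erythritol at 5 min (-0.32 to 0.53) and 20 min (-0.34 to 0.23). Gcn4 targets turned at 5 min of glycerol (-0.29 to 0.12) and in xylitol minus erythritol at 20 min (0.12 to -0.38), and glycolysis at 20 min of sorbitol (-0.25 to 0.02) and in sorbitol minus xylitol (-0.39 to 0.07). Iron at 20 min of erythritol (-0.36 to 0.10), the proteasome at 10 min of glycerol (0.05 to -0.05) and hexose transport in sorbitol minus glycerol at 5 min (-0.30 to 0.08) turned as well. So did heat shock (-0.31 to 0.05) and ribosome biogenesis (0.28 to -0.05) in xylitol minus erythritol at 5 min and NCE103 at 20 min (-2.18 to 0.06). None of the osmostress shifts turned.

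Without the 5 weak arrays (added later) the counts were 14 at 5 min of glycerol, 37, 49, 590 and 836 at 5, 10, 30 and 60 min of sorbitol and 29 at 10 min of xylitol. Differences gave 1, 12 and 99 genes for sorbitol minus glycerol, 1 for erythritol minus glycerol at 10 min, 1 and 8 for xylitol minus erythritol at 10 and 20 min, and 20, 68 and 75 for sorbitol minus xylitol at 10, 20 and 30 min, and the time tests 97 for erythritol, 724 for sorbitol and 97 for xylitol. Leaving out the weak arrays left 1 sorbitol array at 10 min and at 20 min. Counts that involve these groups are not read as results. Msn2/4 targets at 20 min of sorbitol went from 0.19 to -0.03. With poor-flagged spots kept (added later) sorbitol minus glycerol at 20 min gave 35 genes and sorbitol minus xylitol 0 at 10 min and 3 at 20 min.

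With an estimated correlation 75 of 168 list shifts against the reference and 16 of 101 between polyols were called, and 518 of 696 list values were the same and 178 weaker. Against the submitters' own ratios 224 of 411 gene values were the same and 187 had moved. A block for replicate number (correlation 0.0136) moved 0 counts. Deviations of arrays with the same replicate number had a median correlation across genes of 0.01, those with another number -0.01, those in the same scan batch 0.09 and those in another -0.02, so the numbers do not pair.

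Leaving out 1 array gave 36 to 40 genes at 5 min, 196 to 433 at 10 min and 429 to 542 at 20 min of erythritol, with the low values 36, 36 and 40 at 5 min without replicate 1, 2 or 3 and 196 at 10 min without replicate 3. In glycerol the ranges were 0 to 4 (4, 2 and 0 without replicate 1, 2 or 3), 30 to 394 (394, 315 and 30) and 40 to 131 (40 without replicate 2). In sorbitol they were 0 to 5 at 5 min (0, 5 and 0), 3 to 213 at 10 min (213, 79 and 3), 26 to 99 at 20 min (99 and 26), 277 to 564 at 30 min (564 without replicate 1), 251 to 823 at 60 min (823 and 251 without replicate 2 or 3) and 177 to 401 at 90 min (177 without replicate 1). In xylitol they were 8 to 12, 11 to 25 (11 without replicate 1), 115 to 147 (115 without replicate 1) and 213 to 556 (213 without replicate 3).

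For sorbitol minus glycerol the ranges were 0 to 0, 1 to 107 and 0 to 63 at 5, 10 and 20 min, with 107, 65 and 2 at 10 min without replicate 1, 2 or 3 of glycerol, 58 and 33 without replicate 1 or 2 of sorbitol, and at 20 min 2 and 0 without replicate 1 or 2 of glycerol and 3 and 63 without replicate 1 or 2 of sorbitol. For erythritol minus glycerol they were 0 to 1 (1 without replicate 2 of erythritol), 0 to 5 (3, 2 and 5 without replicate 1, 2 or 3 of glycerol) and 34 to 87 (34, 68 and 84 without replicate 1, 2 or 3 of erythritol and 87, 55 and 39 of glycerol). For xylitol minus erythritol they were 0 to 1 (1 each without replicate 2 of erythritol and replicate 1 of xylitol), 0 to 4 (4 without replicate 2 of erythritol) and 0 to 53 (0 and 53 without replicate 1 or 2 of xylitol). For sorbitol minus xylitol they were 0 to 1 at 5 min (1 without replicate 1 of xylitol), 0 to 49 at 10 min (49, 19 and 1 without replicate 1, 2 or 3 of sorbitol and 1, 0 and 1 of xylitol), 0 to 30 at 20 min (2 and 25 of sorbitol, 0 and 30 of xylitol) and 0 to 25 at 30 min (25, 4 and 8 of sorbitol, 5 and 14 without replicate 2 or 3 of xylitol).

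The time tests ranged from 16 to 67 in erythritol (17, 23 and 33 without replicate 1, 2 or 3 at 5 min, 16, 21 and 19 at 20 min), 0 to 23 in glycerol (23 and 3 without replicate 1 or 2 at 10 min), 359 to 636 in sorbitol and 25 to 109 in xylitol (25 without replicate 2 at 5 min, 109 without replicate 2 at 20 min, 25 without replicate 3 at 30 min). List calls ranged from 161 to 172 against the reference and from 92 to 108 between polyols. Reversed when 1 array was left out were sorbitol and xylitol metabolism at 10 min of erythritol (0.17 to -0.02, range -0.02 to 0.23), Msn2/4 targets at 20 min of sorbitol (0.19 to -0.03, range -0.03 to 0.46) and heat shock at 20 min of xylitol (0.19 to -0.02, range -0.02 to 0.46). So were ribosomal proteins in erythritol minus glycerol at 20 min (-0.12 to 0.03, range -0.28 to 0.03) and Gcn4 targets in xylitol minus erythritol at 20 min (0.12 to -0.09, range -0.09 to 0.37). At 60 min of sorbitol BRX1, a ribosome assembly gene, went from -1.46 to 0.00 (range -2.92 to 0.00) and FIG1, a mating gene with neither channel above background, from -1.10 to 0.01 (range -1.75 to 0.01). Of 5329 values 4830 were the same, 112 stronger, 380 weaker and 7 reversed.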

Other observations

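The tests of dye bias and of the tryptophan genes as a set were chosen after the result was seen, and the test of the disrupted locus before. Over time SIP18 and NQM1 changed in erythritol, xylitol and sorbitol, and ALD3 in xylitol and sorbitol. Iron genes were lowest at 90 min of sorbitol, with a list median of -1.37 (blocked -1.45). G1/S genes lay at -0.22 in erythritol at 20 min and -0.13 in sorbitol at 60 min (adjusted p = 0.285 and 0.433), although SPT21 fell in xylitol. In glycerol at 10 min the cyclin CLB5 (-1.40) and the polo kinase CDC5 (-1.27) were called below the reference. Of the 175 calls in that group 143 were falls, against 1 without background correction and 8 with print-tip loess. The falls of CLB5 and CDC5 may thus depend on the processing.

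TRP1 was above the reference in 13 of 16 groups, up to 3.12 at 30 min of xylitol, on 1 array. Dye bias of the probe alone cannot give the change of TRP1 over the sorbitol times (adjusted p = 0.000246, moderated F test) and the erythritol times (0.0156). A constant dye bias beneath that change is not excluded. TRP1 did not pass the same test in xylitol (0.136) or glycerol. A rise of the tryptophan genes as a set can be excluded, because 0 of 52 values of TRP2, TRP3, TRP4 and TRP5 were called up by limma and 5 were called down (TRP4 at -1.85 at 60 min of sorbitol). Over the arrays 99% of genes outside the osmostress list followed its mean less closely than TRP1 did. Reading of the marker from the disrupted GPD1 locus under osmostress control is a hypothesis, and a stress response of the native TRP1 gene would give the same 99%; TRP1 in osmotic stress in a strain without the marker at GPD1 would tell them apart.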
